A study of Homo sapiens with 16 samples.

How the data were processed

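Gene expression was measured on 16 2-colour arrays, 1 for each of 4 cell lines (TMD8, OCI-Ly10, HBL1 and OCI-Ly3) at each of 4 times (6, 12, 24 and 36 h). Per the labels, every array carried Cy5-labelled RNA of cells given ND-2158 and Cy3-labelled RNA of cells given ND-1659, both at 10 µM, so no array has the dyes exchanged. Each line lay on 1 of 4 distinct slides, which held its 4 times. The slides cannot be told from the lines.

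Per the file headers, Agilent Feature Extraction 10.1.1.1 made each array file from a scan of a 4-array slide. It gives an intensity per spot, the mean pixel signal, and the median pixel signal of the local background, on a linear scale without normalization, per the file headers. It also gives a deposited log10 ratio of Cy5 to Cy3 after background subtraction, detrending across the array and dye normalization, per the file headers. Flags of 0 or 1 mark spots well above background, saturated spots and uneven spots, per the file headers. The deposited series value table holds, on a log10 scale, the ratio of the same processed signals, which was found by setting each column against its own array file. All other values are log2 ratios computed here from the deposited intensities. Probe coordinates are on hg19, per the file headers.

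Each array held 45015 spots, 43376 of them for genes and 1639 controls, from 41000 gene probes. Background was corrected with normexp and an offset of 50. On some OCI-Ly3 arrays that fit failed as first planned. A local background above 3 times the array median, found at 65 spots over all arrays, was therefore replaced by that median for the fit and the spot left out. This repair was chosen after seeing the data. Ratios were normalized within arrays by loess with control spots at weight 0, spots with an outlier flag were left out, and the spots of a probe were averaged. A probe was kept when it stood well above background in either channel on at least 4 of the 16 arrays, which left 29659. The probe with the highest mean intensity stood for its gene, which left 21078 genes, 14375 with a symbol, and 78 of them lacked a value on some array. Several kept probes existed for 6186 genes, and some of these disagree. A gene whose Cy3 signal lay below background on every array is given as at least N-fold, from its ratio to the background-level signal. Names came from accessions in the files for 27294 probes, from another accession for 135, from an unchanged symbol for 2279 and from an older symbol for 436, and 10856 kept the name in the file.

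The software was R 4.3.3 with limma 3.58.1 and data.table version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9. All tests on single genes were moderated tests of limma, with adjustment by Benjamini and Hochberg over all genes and a threshold of 0.05. For the mean over times, the 4 line means were tested against 0. Each time was tested against 0 in 1 fit of all 16 arrays with the line as a random block, whose correlation was 0.033. The difference of 36 and 6 h was fitted with the line as a fixed block, which leaves 9 residual degrees of freedom. The lines were compared by an F test with the time as a fixed block. The comparisons, the 28 gene lists (871 genes, 820 measured, 40 of them in over 1 list) and the other settings tried were chosen before the data were examined. The difference of 36 and 24 h was chosen after seeing the data. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation and with fry, adjusted over the 28 lists. Intervals are 95 percent intervals from the same fits. The steps were tested on simulated data of 21000 genes with 200 changed. Of genes changed by a log2 of 1, the fit called 100 percent for the mean over times, 100 at 6 h, 95.5 at 12 h, 98.5 at 24 h, 100 at 36 h, 95.5 for 36 minus 6 h, 89.4 for 36 minus 24 h and 90.9 between the lines. Of genes changed by 0.3 it called 77.6 percent for the mean over times and 34.3 at 36 h.

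Genes with a symbol were named by rule. For the mean over times these were the 12 highest and 12 lowest past the threshold with the same sign in all 4 lines. For each difference of times they were the 10 highest and 10 lowest, and for each single time the 5 highest and 5 lowest. To these came the 10 smallest p-values between the lines, up to 4 called members of each list or its 2 largest where none was called, and 25 genes of the pathway fixed beforehand. The report discusses part of these, chosen with their values in view, whereas the counts over alternatives cover all of them. Settings tried as planned were no background correction, a normexp offset of 10, median centring, scaling between arrays, the scanner software's ratio, the deposited value table, no filter on dim probes, a stricter filter, the mean of a gene's probes, a trended and robust prior, array weights, a fold of 1.5, each line or time left out, other blocks, fits of single times, a slope over log2 time and other list tests. Added after seeing the data were normexp with every background kept, median centring on the tested genes, omission of the OCI-Ly3 24 h array and an exact permutation of list medians over the times or the lines.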

Results

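Gene expression was measured in 4 human lines of activated B cell-like diffuse large B cell lymphoma, an aggressive cancer of mature B cells. The cells were exposed at 10 µM to ND-2158, which the series title places among inhibitors of the kinase IRAK4, or to ND-1659, which the labels call a related negative control. IRAK4 passes signals from Toll-like receptors and the interleukin-1 receptor, through the adaptor MYD88, to NF-kB. The lines TMD8, OCI-Ly10, HBL1 and OCI-Ly3 were sampled at 6, 12, 24 and 36 h, which gave 16 2-colour arrays, 4 at each time. RNA from ND-2158 cells carried Cy5 and RNA from ND-1659 cells of the same line and time carried Cy3. Each value below is a log2 ratio of ND-2158 to ND-1659, so a positive value means higher with ND-2158, and SD is the spread between the 4 lines. No array had the dyes exchanged, so a gene's own dye effect stays in its ratio and cancels only between times or between lines. Between 27636 and 29628 of the 43376 spots for genes stood well above background in Cy5 and between 24186 and 26513 in Cy3, and the number of arrays limits the precision. The labels do not say that the samples came from separate cultures, so the p-values of single genes measure only the spread between these samples. For a list, camera sets its genes against all other genes under a preset correlation of 0.01. Its p-values therefore do not rest on the spread between the 4 lines alone, and the SD printed beside them is a separate measure. In all, 21078 genes were tested.

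Over the mean of the 4 times, IFI44L, IFIT3 and IFIT1 were among the lowest genes with ND-2158. IFI44L was at -0.55 (SD 0.21, n = 4, adjusted p = 0.00157), IFIT3 at -0.50 (SD 0.23, n = 4, adjusted p = 0.00365) and IFIT1 at -0.46 (SD 0.19, n = 4, adjusted p = 0.00312). All 3 code for proteins that interferon induces against viruses. The chemokine genes CCL4 (-0.34, SD 0.12, n = 4, adjusted p = 0.00365) and CCL3 (-0.24, SD 0.07, n = 4, adjusted p = 0.00766) were lower. The cytokine gene TNF was at -0.38 (SD 0.28, n = 4, adjusted p = 0.0196). Lower too was NFKBIZ (-0.28, SD 0.12, n = 4, adjusted p = 0.00884), which codes for a nuclear partner of NF-kB. IRAK4 itself was slightly lower (-0.16, SD 0.04, n = 4, adjusted p = 0.0268), and so was MYD88 (-0.15, SD 0.07, n = 4, adjusted p = 0.0445). Without OCI-Ly10 IRAK4 was at -0.15 (adjusted p = 0.158) and MYD88 at -0.15 (adjusted p = 0.182). Both missed the threshold without TMD8 or HBL1 too, and without the 6, 12 or 24 h arrays, with IRAK4 at -0.16, -0.10 and -0.14 and MYD88 at -0.16, -0.16 and -0.11. MYD88 also missed it without the 36 h arrays (-0.16). CCL3 was at 0.02 without the 24 h arrays and at -0.65 without the 36 h arrays. Over the alternatives the adjusted p of IRAK4 ran from 0.00463 to 0.203 and that of MYD88 from 0.00164, where median centring put it at 0.31, to 0.198. Centring each array on its median spot turned IRAK4 to 0.11, NFKBIZ to 0.09, TNF to 0.09, CCL3 to 0.05 and BTK to 0.17. IFI44L and IFIT3 were below 0 and past the threshold under each scaling, at -0.25 and -0.30 with median centring. BCL2L1, which codes for a survival protein of the BCL2 family, was at -0.30 (SD 0.08, n = 4, adjusted p = 0.00365). Its relative BCL2 was at 0.23 (SD 0.08, n = 4, adjusted p = 0.0106). BTK, a kinase of the B cell receptor, was at -0.23 (SD 0.10, n = 4, adjusted p = 0.0136).

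RPS2, RPL13A and RPL23 were among the highest genes over the mean of the times. RPS2 (0.74, SD 0.10, n = 4, adjusted p = 6.57e-05), RPL13A (0.69, SD 0.12, n = 4, adjusted p = 6.57e-05) and RPL23 (0.67, SD 0.08, n = 4, adjusted p = 6.57e-05) code for proteins of the ribosome. ACTB (0.60, SD 0.07, n = 4, adjusted p = 6.57e-05) codes for actin, and its 4 probes ran from -0.50 to 0.49 at 24 h. DLGAP2, a gene of synaptic scaffolds, is given as at least 1.96-fold higher, because its Cy3 signal lay below background on every array (SD of the log2 ratio 0.36, n = 4, adjusted p = 0.000731). Its probe could pass the filter only through Cy5. Without exchanged dyes, its excess in Cy5 cannot be told apart from an effect of the dye. RGS1, a brake on G protein signalling, was higher too (0.30, SD 0.13, n = 4, adjusted p = 0.00813). By limma's test with false discovery rate adjustment, 2292 genes passed, 1465 higher and 827 lower, and 11 of them differed by 1.5-fold or more. The higher share of 63.9 percent was 80.2 with median centring, 48.5 with centring on the tested genes, 79.3 with the scanner software's own ratio and 77 with the deposited value table. Median centring moved the median of all genes from 0.01 to 0.21, and relative to that shift IRAK4, TNF, NFKBIZ and CCL3 lay below the typical gene and MYD88 above it. The count was 290 without TMD8, 354 without OCI-Ly10 and 476 without the 6 h arrays, against 2729 without OCI-Ly3. It was 1356 without the 12 h arrays and 1326 without the 36 h arrays. Of 91 named genes past the threshold, 25 still passed with the same sign without TMD8, 33 without OCI-Ly10, 68 without HBL1, 81 without OCI-Ly3 and 31 without the 6 h arrays.

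Several genes of the pathway did not pass over the mean of the times, which does not show that the compounds act alike on them. IRAK1, the kinase that IRAK4 phosphorylates, was at -0.07 (95 percent interval -0.16 to 0.01, adjusted p = 0.232). The cytokine gene IL6 was at -0.14 (-0.24 to -0.04, adjusted p = 0.0763) and IL10 at -0.08 (-0.17 to 0.01, adjusted p = 0.219). The plasma cell regulators IRF4 (-0.03, interval -0.12 to 0.05, adjusted p = 0.612) and PRDM1 (0.02, interval -0.07 to 0.10, adjusted p = 0.795) and the growth regulator MYC (-0.04, interval -0.14 to 0.07, adjusted p = 0.646) lay near 0. STAT3, which carries cytokine signals to the nucleus, was at -0.13 (interval -0.24 to -0.01, adjusted p = 0.126).

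Among 28 gene lists, the interferon response had a median of -0.14 over the mean of the times (SD 0.13, n = 4, adjusted p = 6.72e-10 by camera), although median centring put it at 0.21 and centring on the tested genes at 0.01. With an estimated correlation its adjusted p = 0.539. It held 0 higher and 12 lower genes of 40, or 20 lower when adjusted over the list alone. The lines differed, with a mean of the list's array medians of -0.20 in TMD8 and -0.27 in HBL1, but -0.01 in OCI-Ly10 and -0.05 in OCI-Ly3. NF-kB targets had a median of -0.10 (SD 0.05, n = 4, adjusted p = 2.34e-08, adjusted p = 0.419 with an estimated correlation) and were at 0.27 and 0.07 under those same centrings. They held 3 higher and 14 lower genes of 47, or 4 and 20 over the list alone. Chemokines and cytokines were at -0.07 (adjusted p = 0.00266, adjusted p = 0.419 with an estimated correlation; 0.02 with median centring). Cytosolic ribosomal proteins were at 0.32 (SD 0.09, n = 4, adjusted p = 9.28e-32, adjusted p = 0.419 with an estimated correlation), with 40 of 47 genes higher and 44 over the list alone. Lists of equal brightness had a median of 0.29, so most of that rise was shared with other bright genes. G1/S and DNA replication was at -0.05 (adjusted p = 0.00124, adjusted p = 0.561 with an estimated correlation) and G2/M and mitosis at -0.05 (adjusted p = 0.000457, adjusted p = 0.444 with an estimated correlation). Apoptosis regulators were at -0.08 (adjusted p = 0.00653, adjusted p = 0.419 with an estimated correlation), and the amino acid stress and unfolded protein response at -0.05 (adjusted p = 0.00653, adjusted p = 0.444 with an estimated correlation). These 4 lists turned above 0 with median centring, at 0.41, 0.35, 0.35 and 0.35. The stress list lost its call without OCI-Ly3 (-0.03, adjusted p = 0.0659). The list of apoptosis regulators did not move as 1 group, since it holds both the higher BCL2 and the lower BCL2L1. Over all alternatives the adjusted p of the called lists ran from 5.22e-41 to 0.781.

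The other 20 lists did not pass over the mean of the times. JAK-STAT3 targets were at -0.04, TLR, IL-1R and IRAK pathway components at -0.04 (adjusted p = 0.111), BCR signalling components at 0.01 and germinal centre and B cell identity genes at 0.05. Plasma cell differentiation was at -0.03, MYC targets and ribosome biogenesis at 0.02, p53 targets at -0.02, cytosolic heat shock response at -0.06 and cholesterol and fatty acid synthesis at -0.03. Cholesterol efflux targets were at 0.03, glycolysis and hypoxia at 0.02, oxidative phosphorylation at -0.03, histones at 0.03 and aryl hydrocarbon receptor and NRF2 targets at -0.01. MHC class II presentation was at -0.02, MHC class I presentation at -0.06, immediate early and MAPK feedback genes at -0.01, T and NK cell markers at 0.03, myeloid cell markers at 0.02 and erythroid, stromal and epithelial markers at 0.01. Single members still passed, such as the heat shock chaperone HSP90AA1 (-0.27, SD 0.10, n = 4, adjusted p = 0.00711; 0.37 with median centring) and the hypoxia gene ADM (0.37, SD 0.19, n = 4, adjusted p = 0.00815).

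At 6 h, ribosomal genes were higher and none of the 25 genes fixed for the pathway passed. NPM1, which codes for a nucleolar protein of ribosome assembly, was at 0.44 (SD 0.20, n = 4, adjusted p = 0.00974). The ribosomal genes RPS2 (0.79, SD 0.10, n = 4, adjusted p = 0.000117) and RPS27 (0.60, SD 0.05, n = 4, adjusted p = 0.000321) were higher. SUMO2, which codes for a small protein modifier, was at -0.32 (SD 0.13, n = 4, adjusted p = 0.0158), and SPPL3, a membrane protease gene, at -0.34 (SD 0.14, n = 4, adjusted p = 0.0457), but median centring put them at 0.27 and 0.03. TNF (-0.47, SD 0.77, n = 4, adjusted p = 0.534) and CCL3 (-0.31, SD 0.78, n = 4, adjusted p = 0.577) varied widely between the lines. In all, 128 genes passed, 123 higher and 5 lower, but 599 passed without OCI-Ly3, 18 without TMD8, 29 without OCI-Ly10, 28 without HBL1 and 37 with only the 6 h arrays. Of 13 named genes past the threshold, 5 still passed without TMD8, 6 without OCI-Ly10, 6 without HBL1 and 11 without OCI-Ly3. The higher share of 96.1 percent was 82 with median centring, 42.1 with centring on the tested genes and 82 with the deposited table. NF-kB targets were at -0.15 (SD 0.23, n = 4, adjusted p = 7.42e-06, adjusted p = 0.708 with an estimated correlation), with 0 of their genes called by limma. With median centring they lay at 0.18, beside 0.20 for all genes. Their medians with loess were -0.16 in TMD8, -0.43 in OCI-Ly10, -0.15 in HBL1 and 0.14 in OCI-Ly3, and the list lost its call without OCI-Ly10 (-0.04, adjusted p = 0.145). Cytosolic ribosomal proteins were at 0.31 (adjusted p = 2.61e-34, adjusted p = 0.256 with an estimated correlation), with 23 of 47 genes higher and 40 over the list alone. The adjusted p of the lists called at 6 h ran from 2.54e-37 to 0.708 over the alternatives.

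At 12 h, CDKN2C, AGO2 and SLFN11 were among the lowest genes past the threshold. CDKN2C, which codes for an inhibitor of the G1 kinases, was at -0.68 (SD 0.32, n = 4, adjusted p = 0.0467). AGO2, the slicer of small RNA silencing, was at -0.51 (SD 0.19, n = 4, adjusted p = 0.0105). SLFN11, a gene of the replication stress response, was at -0.53 (SD 0.16, n = 4, adjusted p = 0.0199). B2M, the light chain of MHC class I, was at -0.33 (SD 0.08, n = 4, adjusted p = 0.0452; 0.34 with median centring). PLCG2, a phospholipase of the B cell receptor, was at 0.34 (SD 0.07, n = 4, adjusted p = 0.0254). IRAK4 (-0.36, adjusted p = 0.0656) and CCL3 (-0.60, adjusted p = 0.156) missed the threshold. The test called 291 genes, 201 higher and 90 lower, and 16 without TMD8, 19 without OCI-Ly10 and 32 without HBL1. It called 84 with every local background kept and 2 with only the 12 h arrays. Of 19 named genes past the threshold, 6 still passed without TMD8, 7 without OCI-Ly10 and 10 without HBL1. The higher share of 69.1 percent was 85.7 with median centring and 44.8 with centring on the tested genes. The interferon response was at -0.20 (SD 0.14, n = 4, adjusted p = 6.67e-11, adjusted p = 0.425 with an estimated correlation), but at 0.09 with median centring. NF-kB targets were at -0.14 (SD 0.05, n = 4, adjusted p = 1.4e-09, adjusted p = 0.425 with an estimated correlation), but at 0.17 with median centring. G1/S and DNA replication was at -0.16 (adjusted p = 1.02e-10, adjusted p = 0.429 with an estimated correlation), but at 0.26 with median centring. The median of all genes was 0.19 with that centring, so the interferon and NF-kB lists still lay below it and G1/S lay above it. All 3 lists held 0 genes called by limma among all genes, against 7, 2 and 5 lower genes over each list alone. Over the alternatives the adjusted p of the 10 lists called at 12 h ran from 1.31e-38 to 0.841.

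At 24 h, CCL3, CCL4 and NFKBIA were lower with ND-2158. CCL3 was at -1.04 (SD 0.36, n = 4, adjusted p = 0.00939), its copy CCL3L3 at -0.96 (SD 0.50, n = 4, adjusted p = 0.0241) and CCL4 at -0.86 (SD 0.25, n = 4, adjusted p = 0.0141). These genes code for attractants of T cells and macrophages. NFKBIA, which codes for the inhibitor that holds NF-kB in the cytoplasm and is itself an NF-kB target, was at -0.64 (SD 0.32, n = 4, adjusted p = 0.03). The cytokine genes LTA (-0.68, SD 0.32, n = 4, adjusted p = 0.015), EBI3 (-0.69, SD 0.41, n = 4, adjusted p = 0.035) and IL6 (-0.44, SD 0.30, n = 4, adjusted p = 0.0294) were lower. So were STAT3 (-0.39, SD 0.31, n = 4, adjusted p = 0.0461) and the checkpoint ligand CD274 (-0.52, SD 0.23, n = 4, adjusted p = 0.0113), although the 2 probes of CD274 were at -0.52 and -0.03. Lower as well were the early growth response gene EGR1 (-1.0, SD 0.57, n = 4, adjusted p = 0.031) and BCL2L1 (-0.51, SD 0.24, n = 4, adjusted p = 0.024). FOXM1, a driver of mitotic genes, was at -0.38 (SD 0.19, n = 4, adjusted p = 0.024), but at 0.01 with median centring. Higher genes included IL4R, the interleukin-4 receptor (0.53, SD 0.37, n = 4, adjusted p = 0.0168), and TNFRSF17, the plasma cell receptor BCMA (0.56, SD 0.27, n = 4, adjusted p = 0.0335). CCL3 was at -0.78 with median centring and past the threshold without OCI-Ly10, HBL1 or OCI-Ly3, but not without TMD8 (-1.1, adjusted p = 0.0652) or with the 4 arrays of 24 h alone (adjusted p = 0.0738). Over the alternatives its adjusted p ran from 0.00531 to 0.0738.

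The test called 1506 genes at 24 h, 930 higher and 576 lower, of which 64 reached 1.5-fold. The higher share of 61.8 percent was 86.9 with median centring, 47.5 with centring on the tested genes and 72.2 with the scanner software's ratio. It called 201 without TMD8, 253 without OCI-Ly10 and 696 without the OCI-Ly3 24 h array alone, on which 254 genes differed by 2-fold or more. Of 66 named genes past the threshold, 9 still passed without TMD8, 14 without OCI-Ly10, 32 without HBL1, 35 without OCI-Ly3 and 24 without its 24 h array. With only the 4 arrays of 24 h limma called 0 genes, with 3430 at unadjusted p under the threshold. NF-kB targets were at -0.29 (SD 0.10, n = 4, adjusted p = 1.77e-16, adjusted p = 0.304 with an estimated correlation), below 0 in each line at -0.23, -0.19, -0.41 and -0.21, but at 0.05 with median centring. The median of all genes was 0.18 with that centring. The list held 0 higher and 12 lower genes of 47, or 2 and 24 over the list alone. Lists of equal brightness had a median of -0.01. JAK-STAT3 targets were at -0.17 (adjusted p = 0.0011, adjusted p = 0.324 with an estimated correlation; 0.05 with median centring), although IL4R among them was higher. G2/M and mitosis was at -0.19 (adjusted p = 3.14e-09, adjusted p = 0.404 with an estimated correlation; 0.21 with median centring), with 10 lower genes of 46 and 13 over the list alone. MHC class I presentation was at -0.16 (adjusted p = 0.000224, adjusted p = 0.361 with an estimated correlation; 0.20 with median centring), with B2M at -0.50 (SD 0.22, n = 4, adjusted p = 0.0017), although the 2 probes of B2M were at -0.50 and 0.10. The interferon response was at -0.19 (adjusted p = 7.28e-06, adjusted p = 0.519 with an estimated correlation; 0.14 with median centring), from -0.70 in HBL1 to 0.11 in OCI-Ly3, and without HBL1 it was at -0.04 (adjusted p = 0.228). Germinal centre and B cell identity genes were at 0.11 (adjusted p = 0.033, adjusted p = 0.422 with an estimated correlation) and lost their call without OCI-Ly10 (0.10, adjusted p = 0.103). Over the alternatives the adjusted p of the 16 lists called at 24 h ran from 6.12e-66 to 0.937.

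**Figure D1:**
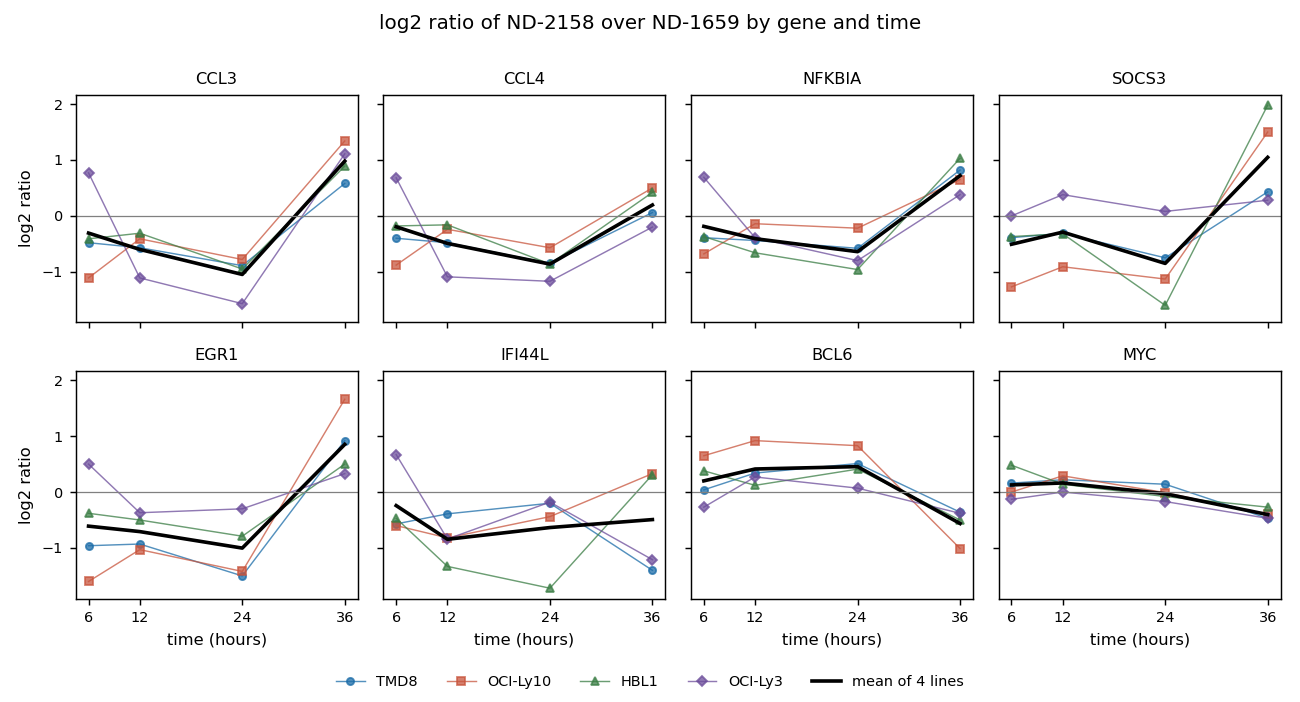
Log2 ratio of ND-2158 to ND-1659 (vertical axis) against hours of exposure (horizontal axis) for 8 genes, with 1 thin line per cell line and the mean of the 4 lines in bold. CCL3, NFKBIA, SOCS3 and EGR1 lie below 0 at 24 h and above 0 at 36 h.

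At 36 h, NF-kB targets lay above 0 instead. CCL3 was at 0.98 (SD 0.32, n = 4, adjusted p = 0.0256), EBI3 at 0.92 (SD 0.56, n = 4, adjusted p = 0.0198) and NFKBIA at 0.72 (SD 0.28, n = 4, adjusted p = 0.0347). JUNB, a subunit of the AP-1 transcription factor, was at 0.52 (SD 0.10, n = 4, adjusted p = 0.00661). MALT1, the protease that links the B cell receptor to NF-kB, was at 0.50 (SD 0.13, n = 4, adjusted p = 0.00297). MYC was at -0.40 (SD 0.09, n = 4, adjusted p = 0.0174) and the B cell receptor chain CD79B at -0.53 (SD 0.20, n = 4, adjusted p = 0.0347), although median centring put them at 0.20 and 0.02. The median of all genes was 0.24 with that centring. The inflammasome gene NLRP7 (-1.40, SD 0.69, n = 4, adjusted p = 0.00297) and the antibody joining chain JCHAIN (-0.84, SD 0.69, n = 4, adjusted p = 0.0439) were lower. So were the lymphocyte surface gene CD52 (-0.72, SD 0.56, n = 4, adjusted p = 0.0242) and the MHC class II loader HLA-DMB (-0.60, SD 0.38, n = 4, adjusted p = 0.0267). CCL3, NFKBIA, JUNB and EBI3 were above 0 under every scaling but lost their calls without TMD8, OCI-Ly10 or HBL1, with CCL3 at 1.11, 0.86 and 1.01 and NFKBIA at 0.69, 0.74 and 0.62. In all, 419 genes passed, 281 higher and 138 lower, against 29 without TMD8, 29 without OCI-Ly10 and 64 without HBL1. The count was 160 with every local background kept and 3 with only the 36 h arrays. Of 39 named genes past the threshold, 7 still passed without TMD8, 6 without OCI-Ly10, 10 without HBL1 and 32 without OCI-Ly3. The higher share of 67.1 percent was 80.5 with median centring and 42.7 with centring on the tested genes. These directions at 36 h follow the labels. An exchange of the RNA of the compounds before labelling of the 36 h arrays was not excluded. Such an exchange would make the 281 genes lower and the 138 higher, and 67.1 percent would then be the lower share.

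NF-kB targets as a list were at 0.17 at 36 h (SD 0.10, n = 4, adjusted p = 1.44e-07, adjusted p = 0.67 with an estimated correlation), at 0.12, 0.19, 0.32 and 0.08 in the 4 lines, and at 0.63 with median centring. They held 5 higher genes of 47, or 9 higher and 1 lower over the list alone. Immediate early and MAPK feedback genes were at 0.12 (adjusted p = 0.00327 by camera) and JAK-STAT3 targets at 0.12 (adjusted p = 0.0107 by camera), each at adjusted p = 0.67 with an estimated correlation. Each was above 0 under median centring too, but the median of all genes was then 0.24, so that sign decides little. The JAK-STAT3 list missed the threshold without OCI-Ly10 (0.10, adjusted p = 0.0612) or HBL1 (0.12, adjusted p = 0.14). Germinal centre and B cell identity genes were at -0.17 (adjusted p = 0.000474, adjusted p = 0.67 with an estimated correlation; 0.22 with median centring) with 0 members called by limma, or 3 lower over the list alone. MHC class II presentation was at -0.13 (adjusted p = 0.0052, adjusted p = 0.792 with an estimated correlation; 0.29 with median centring), with HBL1 at -0.53, and was at -0.02 without HBL1 (adjusted p = 0.412). MHC class I presentation was at 0.08 (adjusted p = 0.0107, adjusted p = 0.67 with an estimated correlation), led by HLA-C (0.47, SD 0.16, n = 4, adjusted p = 0.0054), and lost its call without HBL1 (0.05, adjusted p = 0.114). Glycolysis and hypoxia was at 0.15 (adjusted p = 0.0107, adjusted p = 0.792 with an estimated correlation), at 0.49 in OCI-Ly3, and was at -0.01 without that line (adjusted p = 0.698). The interferon response was at -0.12 (adjusted p = 0.00299, adjusted p = 0.792 with an estimated correlation; 0.21 with median centring), but at 0.14 in OCI-Ly10 and 0.17 in HBL1, and it missed the threshold without TMD8 (-0.05, adjusted p = 0.273) or OCI-Ly3 (-0.05, adjusted p = 0.275). With an estimated correlation the adjusted p of the 11 lists called at 36 h ran from 0.67 to 0.792, and over all alternatives from 3.19e-18 to 0.973.

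**Figure D2:**
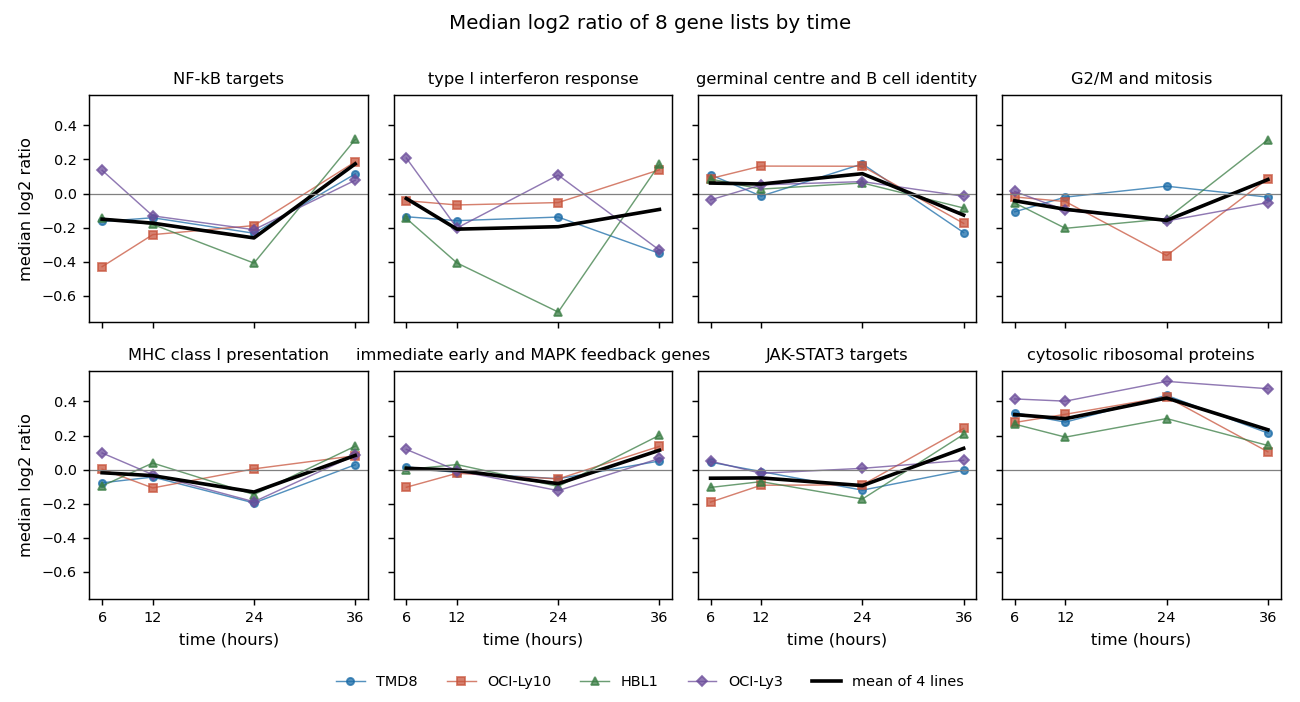
Median log2 ratio of ND-2158 to ND-1659 over the genes of 8 lists (vertical axis) against hours of exposure (horizontal axis), with 1 thin line per cell line and the mean of the lines in bold. NF-kB targets lie below 0 at 24 h and above 0 at 36 h in all 4 lines, although median centring puts their 24 h median at 0.05, beside 0.18 for all genes.

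The difference between 36 and 24 h, chosen after the data had been seen, was free of constant dye effects. CCL3 rose by 2.02 (SD 0.51, n = 4, adjusted p = 0.0115). SOCS3, the feedback inhibitor of STAT3 signalling, rose by 1.90 (SD 1.5, n = 4, adjusted p = 0.0239) and EGR1 by 1.86 (SD 1.1, n = 4, adjusted p = 0.0193). NFKBIA rose by 1.36 (SD 0.48, n = 4, adjusted p = 0.0166) and the adhesion gene ICAM1 by 1.16 (SD 0.60, n = 4, adjusted p = 0.0204). STAT3 rose by 0.62 (SD 0.25, n = 4, adjusted p = 0.0466) and B2M by 0.61 (SD 0.27, n = 4, adjusted p = 0.0181). BCL6, the repressor that maintains germinal centre B cells, fell by 1.02 (SD 0.59, n = 4, adjusted p = 0.0212), CD79B by 0.87 (SD 0.24, n = 4, adjusted p = 0.0239) and NLRP7 by 2.10 (SD 1.13, n = 4, adjusted p = 0.00749). BCL6 had missed the threshold at 24 h itself (0.46, adjusted p = 0.0695) and at 36 h (-0.56, adjusted p = 0.0607). The test called 738 genes, 343 higher and 395 lower, against 0 without TMD8, 17 without OCI-Ly10, 127 without HBL1 and 208 without the OCI-Ly3 24 h array. It called 177 with median centring and 267 with the scanner software's ratio. Of 68 named genes past the threshold, 0 still passed by limma without TMD8, 3 without OCI-Ly10, 8 without HBL1, 49 without OCI-Ly3 and 29 without its 24 h array. With only the 8 arrays of these times limma called 0, with 2913 at unadjusted p under the threshold.

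NF-kB targets rose by 0.44 between 24 and 36 h (SD 0.19, n = 4, adjusted p = 4.7e-18, adjusted p = 0.232 with an estimated correlation), by 0.41, 0.35, 0.74 and 0.34 in the 4 lines. They held 8 higher and 0 lower genes, or 24 and 1 over the list alone, and the rise was 0.44 to 0.51 under the scalings. G2/M and mitosis rose by 0.28 (adjusted p = 6.14e-09, adjusted p = 0.497 with an estimated correlation) and JAK-STAT3 targets by 0.28 (adjusted p = 0.000155, adjusted p = 0.379 with an estimated correlation). The G2/M median did not rise in TMD8, at 0.04 at 24 h and -0.02 at 36 h, but rose in the other lines. MHC class I presentation rose by 0.27 (adjusted p = 3.34e-06) and immediate early genes by 0.22 (adjusted p = 0.000223), each at adjusted p = 0.232 with an estimated correlation. Germinal centre and B cell identity genes fell by 0.20 (adjusted p = 0.000904, adjusted p = 0.352 with an estimated correlation) and cytosolic ribosomal proteins by 0.17 (adjusted p = 5.18e-08, adjusted p = 0.435 with an estimated correlation). Lists as bright as the ribosomal one were at -0.12, so most of the ribosomal fall was shared with other bright genes. IL4R fell by 0.90 while the JAK-STAT3 list that holds it rose, and TNFRSF17 fell by 1.06 while the plasma cell list lay at 0.02 and was not called. With an estimated correlation the adjusted p of the 15 lists called ran from 0.232 to 0.735, and over all alternatives from 4.61e-25 to 0.921. Of the genes called at both times, 89 were higher at both, 1 was lower at both and 40 had opposite signs. The all-gene correlation of the 24 and 36 h arrays was -0.39 in OCI-Ly10, -0.30 in HBL1, -0.07 in TMD8 and -0.02 in OCI-Ly3, and the direction was left as the labels state the dyes.

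**Figure D3:**
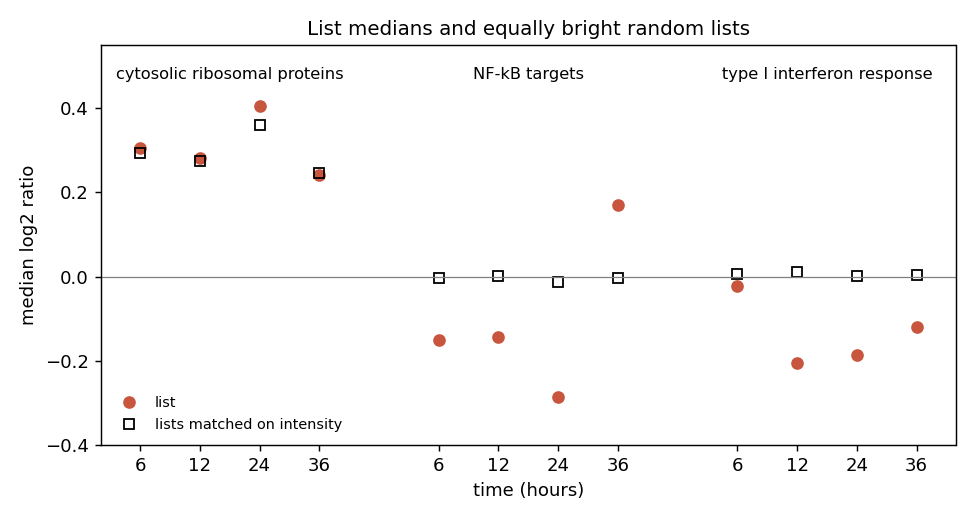
Median log2 ratio of 3 gene lists (vertical axis) at each time in hours (horizontal axis), beside the medians of random lists of equal brightness. Ribosomal protein genes lie close to their matched lists, whereas NF-kB targets lie below theirs at 24 h and above at 36 h. Under median centring the 24 h median of NF-kB targets is 0.05, beside 0.18 for all genes.

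Between 36 and 6 h, no single gene passed. MYC was at -0.53 (SD 0.19, n = 4, adjusted p = 0.159; 95 percent interval -0.75 to -0.31) and CCL3 at 1.29 (SD 0.87, n = 4, adjusted p = 0.319). SOCS3 was at 1.56 (adjusted p = 0.332), NFKBIA at 0.91 (adjusted p = 0.355) and TNFAIP3, an NF-kB feedback enzyme, at 0.49 (interval 0.19 to 0.79, adjusted p = 0.359). By limma 0 genes passed, with 1916 at unadjusted p under the threshold and a smallest adjusted p of 0.0523, and 309 passed without OCI-Ly3. NF-kB targets were at 0.29 (SD 0.31, n = 4, adjusted p = 1.15e-13, adjusted p = 0.76 with an estimated correlation), but at -0.13 in OCI-Ly3, and held 0 called genes, or 8 higher over the list alone. Germinal centre and B cell identity genes were at -0.24 (adjusted p = 0.000557). Of 14 lists called, 11 were higher and 3 lower, with an adjusted p of 0.76 for each under an estimated correlation and of 1.18e-18 to 0.854 over all alternatives.

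Between the lines, CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, came closest, at -0.52 in TMD8, -0.02 in OCI-Ly10, 0.37 in HBL1 and 0.14 in OCI-Ly3 (adjusted p = 0.103). Set against the other 3 lines by limma, a comparison that was not planned, TMD8 had CYP1A1 lower by 0.69 (adjusted p = 0.0254) as its 1 call, and OCI-Ly10, HBL1 and OCI-Ly3 had 0 each, with 777, 1633 and 2756 genes at unadjusted p under the threshold. SREBF1, a regulator of lipid synthesis, was at 0.26 in TMD8 and -0.26 in OCI-Ly3 (adjusted p = 0.37). By limma 0 genes passed, with 1792 at unadjusted p under the threshold, against 1081 with median centring, 1263 with centring on the tested genes, 601 with the deposited table and 43 with the scanner software's ratio. Cytosolic ribosomal proteins differed by exact permutation (p = 0.00166, adjusted p = 0.0466), highest in OCI-Ly3 at 0.45 and at 0.32, 0.28 and 0.22 in TMD8, OCI-Ly10 and HBL1. Each line was hybridised on its own slide, so lines and slides cannot be told apart.

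The files give 1 hg19 position for each probe below, and the probe sequences were not realigned. CCL3 was read by 1 probe on chromosome 17 from 34415891 to 34415949 and CCL4 by 1 on chromosome 17 from 34432718 to 34432777. NFKBIA was read on chromosome 14 from 35870788 to 35870847, IRAK4 by the brighter of its 2 probes on chromosome 12 from 44181174 to 44181233 and IFI44L on chromosome 1 from 79107590 to 79107649. RPS2 was read by 6 probes whose 24 h ratios ran from -0.35 to 0.85, and BST2 by 2 at -0.80 and 0.01. The 24 h ratios of the 6 probes of NPM1 ran from -0.23 to 0.41, those of the 4 of HSP90AA1 from -0.51 to 0.14 and those of the 4 of STAT3 from -0.39 to 0.02. At the same time the 2 probes of BCL2L1 were at -0.51 and -0.17, and the 3 of RRM2 ran from -0.40 to -0.06.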

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

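The tests of the 36 and 24 h difference, its splits included, of the ribosomal genes, of the exchanged samples and of the wide OCI-Ly3 array were chosen only after the results were seen. The tests over other splits of the samples were planned for the remaining comparisons.

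NF-kB targets had a mean list median of -0.26 at 24 h and 0.17 at 36 h, with all 4 lines of opposite sign. With median centring the list was at 0.05 at 24 h, beside 0.18 for all genes. With loess the mean was -0.17 at 12 h against 0.17 at 36 h, again with all 4 lines of opposite sign. The difference of 24 and 36 h was tested (0.44, adjusted p = 4.7e-18 by camera, adjusted p = 0.232 with an estimated correlation). That of 12 and 36 h was not tested. The difference of 36 and 24 h called 738 genes, with CCL3 at 2.02, SOCS3 at 1.90, NFKBIA at 1.36, JUNB at 0.70, STAT3 at 0.62 and BCL6 at -1.02. Of the 35 splits of the 8 arrays 1, the real one, gave as many, with 1 gene at most in the others, the 7 others that part all 4 pairs included. The fit pairs the arrays by line, and the 8 splits that part all pairs are too few for a share under 0.05. The splits therefore cannot decide whether the count arose by chance. An exchange of the channels in the 36 h files is excluded by spike-in slopes of 0.866 to 0.899 with the sign of the other arrays, and loess as the whole cause by a lowest line median of 0.234 without it, against 0.338 with it. An exchange of the RNA of the 2 compounds before labelling of the 36 h arrays cannot be told apart from a return of the pathway, since it leaves the spike-ins as they are, and the correlation of the 24 and 36 h means over the list's 47 genes was -0.543. A return of NF-kB output above that of the control compound may be the cause, which was not tested and would need fresh samples of 36 h or another assay of NF-kB.

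Cytosolic ribosomal proteins were above 0 on 16 of 16 arrays and differed between the lines (adjusted p = 0.0466 by exact permutation). Lists of equal brightness had a median of 0.292 against 0.316, so an intensity trend left after loess fits most of the rise, and 325 of 10000 matched lists reached 0.316. The list stood at percentile 96.51 of its matched lists at 24 h but at 69.81 at 6 h, 53.36 at 12 h and 42.47 at 36 h, so the trend as the whole of the rise stays open. Probes of 1 gene spread by 0.118 (SD) against 0.0956 between lines in 32 genes, as a dye bias of single probes or cross-hybridisation would give. That comparison does not single out such a cause, and 92 of the 106 kept probes of the list had a mean log2 ratio above 0. A dye bias common to the list, in the absence of exchanged dyes, cannot be told apart from a change in expression.

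The OCI-Ly3 array of 24 h had 254 genes that differed by 2-fold or more, against 57 at most on the other arrays. The median SD between replicate spots was 0.031, within the 0.026 to 0.041 of the other arrays. It covers 187 probes, all brighter than the median probe. These values argue against spot noise as the cause for bright probes, but noise of dim probes was not measured. The median Cy5 signal of the array, 98.3, was the lowest of all arrays. A response particular to that line and time, a fault of that sample or noise of dim probes stays open, as 1 array cannot tell them apart.

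Single lines lay apart from the other 3 in 9 of 216 groups of 4 arrays, where chance gives about 1 in 20, or 10.8. At 6 h these were germinal centre and B cell identity genes in OCI-Ly3 (-0.04 against 0.08 to 0.11), cholesterol and fatty acid synthesis in OCI-Ly3 (-0.15 against 0.04 to 0.05), T and NK cell markers in OCI-Ly10 (0.12 against -0.01 to 0.00) and IFIT1 in OCI-Ly3 (0.60 against -0.51 to -0.40). At 12 h it was G1/S and DNA replication in OCI-Ly10 (-0.30 against -0.11 to -0.08), and at 24 h TNF in OCI-Ly3 (0.29 against -1.14 to -0.97). At 36 h these were BCR signalling components in HBL1 (-0.15 against 0.03 to 0.06), JUNB in TMD8 (0.37 against 0.56 to 0.58) and the SD of all log2 ratios in TMD8 (0.167 against 0.217 to 0.225). All 4 lines had opposite signs at 24 and 36 h for germinal centre and B cell identity genes (0.12 and -0.13), the amino acid stress and unfolded protein response (-0.13 and 0.08) and immediate early genes (-0.08 and 0.11), and at 12 and 36 h for the stress response (-0.07 and 0.08), of which that of 12 and 36 h was not tested. The differences of 24 and 36 h were tested by camera, with adjusted p = 0.000904, 1.89e-05 and 0.000223 for the 3 lists, and adjusted p = 0.352, 0.232 and 0.232 with an estimated correlation. With median centring all 3 lists were above 0 at both 24 and 36 h, at 0.45 and 0.22, 0.26 and 0.58, and 0.11 and 0.39. The median of all genes was then 0.18 and 0.24 at these times.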

How the results depend on the processing

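Tests with the OCI-Ly3 24 h array left out, with every local background kept, with centring on the tested genes and of 36 minus 24 h were chosen only after the data were seen, and the others were planned. Leaving out TMD8, OCI-Ly10, HBL1 or OCI-Ly3 in turn gave 290 to 2729 genes over the mean of the times, against 2292 with all lines. The ranges were 18 to 599 at 6 h (128 with all), 16 to 338 at 12 h (291), 201 to 1092 at 24 h (1506), 29 to 406 at 36 h (419), 0 to 309 for 36 minus 6 h (0) and 0 to 846 for 36 minus 24 h (738). The lowest came without TMD8 in every one of these where a gene had been called, and OCI-Ly10 gave 29 at 36 h as well. Leaving out a time gave 476 to 2102 genes for the mean over times, lowest without 6 h, and 0 to 9 between the lines, highest without 36 h. List calls with a line left out ran from 8 to 11 over the mean of the times (8 with all), 2 to 10 at 6 h (5), 9 to 13 at 12 h (10), 12 to 15 at 24 h (16), 8 to 13 at 36 h (11), 10 to 15 for 36 minus 6 h (14) and 14 to 16 for 36 minus 24 h (15).

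With the scanner software's ratio 857 genes passed over the mean of the times, 43 between the lines and 267 for 36 minus 24 h, and with the deposited values 395, 601 and 264. That ratio called 4 lists at 36 h. Array weights gave 6288 genes over the mean of the times, 1135 at 6 h, 954 at 12 h, 1292 at 36 h and 2 between the lines. Scaling between arrays gave 294 at 6 h, 775 at 24 h and 674 at 36 h. A fold of 1.5 as a second condition left 11 genes over the mean of the times, 16 at 6 h, 15 at 12 h, 64 at 24 h, 27 at 36 h and 260 for 36 minus 24 h. Fits of single times gave 37 at 6 h, 2 at 12 h, 0 at 24 h by limma with 3430 at unadjusted p under the threshold, and 3 at 36 h. A fit of the 8 arrays of 24 and 36 h gave 0 by limma, with 2913 at unadjusted p under the threshold. Keeping every local background gave 84 genes at 12 h and 160 at 36 h. Without the OCI-Ly3 24 h array 696 genes passed at 24 h and 208 for 36 minus 24 h. For 36 minus 6 h, 1 gene passed without the filter on dim probes and 1 with the mean of a gene's probes. Between the lines, 5 passed with a normexp offset of 10, 2 with a trended and robust prior and 1 without the time block. Why these counts moved was not tested.

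Treating all 16 arrays as samples gave 3903 genes over the mean of the times with the line as a random block and 4034 with no block, because 16 arrays then stood for 4 lines. Without the block on the line, 124 genes passed at 6 h, 275 at 12 h, 1509 at 24 h, 415 at 36 h, 0 for 36 minus 6 h by limma and 870 for 36 minus 24 h, and of the named genes 5 lost and 2 gained a call. With an estimated correlation camera called 0 lists over the mean of the times, 0 at 6 h, 0 at 12 h, 0 at 24 h, 0 at 36 h, 0 for 36 minus 6 h and 0 for 36 minus 24 h. The test fry called 2, 1, 0, 2, 0, 0 and 0 in the same order. On simulated data with 2 lists shifted by 0.3, each of the 3 list tests called both. The simulated genes varied independently and the lists were drawn at random. The simulation therefore does not show how the 3 tests behave on lists of correlated genes.

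Replacing loess by median centring raised most genes on each array, and the median of all genes was then 0.20 at 6 h, 0.19 at 12 h, 0.18 at 24 h and 0.24 at 36 h. This centring moves each array by 1 value, set on all spots for genes, so it leaves any trend of the ratio with intensity in place. Over the mean of the times it put all genes at 0.21, against 0.01 with loess and 0.01 with the scanner software's ratio. A value above 0 with it can therefore still lie below the typical gene. Median centring called 14345 genes over the mean of the times, 9709 at 6 h, 8728 at 12 h, 8775 at 24 h, 12248 at 36 h, 1081 between the lines and 177 for 36 minus 24 h. It called 16 lists over the mean of the times and 15 at 6 h. Counting genes past the threshold under loess or this centring and lists past it under both, 124 cases over the comparisons had the opposite sign. Over the mean of the times this put AHSA1 at 0.06, BST2 0.06, TNF 0.09, TAGAP 0.03, TNPO1 0.15, IRAK4 0.11, IRAK1 0.30, MYD88 0.31 and NFKBIZ 0.09. For that mean it put NFKBIA at 0.43, TNFAIP3 0.30, CCL3 0.05, STAT3 0.23, PIM1 0.49, IRF4 0.51, SPIB 0.74, MYC 0.54 and CD83 0.40. Still over the 4 times it put BCL2A1 at 0.45, MX1 0.48, CDKN1A 0.36, MCL1 0.41, LTB 0.21, BTK 0.17, HERPUD1 0.46, SSR4 0.42 and MCM7 0.55. With all times averaged it put LIG1 at 0.31, RRM2 0.25, EXO1 0.24, CDK1 0.24, KIF4A 0.19, KIF11 0.26, BUB1B 0.29, PLK3 0.30 and ATF5 0.22. Over all times it put HSPA5 at 0.20, HSP90AA1 0.37, DNAJA1 0.45, SREBF2 0.26, SDHC 0.05, ATP5F1B 0.50, NDUFA9 0.31, H2AX 0.37 and PGD 0.34. Again for the mean it put CD74 at 0.25, B2M 0.46, GZMA -0.06, VCAN -0.08, G1/S and DNA replication 0.41, G2/M and mitosis 0.35, apoptosis regulators of the BCL2 and IAP families 0.35 and amino acid stress response (ATF4) and unfolded protein response 0.35. At 6 h this put SPPL3 at 0.03, SUMO2 0.27, PLEKHG2 0.12, CHMP7 0.03, IRAK1 0.26, MYD88 0.35, PIM1 0.45, IRF4 0.45 and SPIB 0.60. Also at 6 h it put CD83 at 0.42, BCL2A1 0.39, MCL1 0.34, MCM7 0.53, BBC3 0.29, BAX 0.21, H2AX 0.35, DUSP2 0.29 and amino acid stress response (ATF4) and unfolded protein response 0.33. At 12 h this put MYD88 at 0.32, PIM1 0.47, CD83 0.42, BCL2A1 0.36, JUNB 0.41, EAF2 0.01, CEBPG 0.02, B2M 0.34 and G2/M and mitosis 0.30. Also at 12 h it put oxidative phosphorylation at 0.53 and MHC class I presentation 0.36. At 24 h this put MYD88 at 0.18, PIM1 0.56, IRF4 0.36, SPIB 0.71, MYC 0.58, MX1 0.56, LAT2 0.14, PIK3CD 0.05 and EAF2 0.10. Also at 24 h it put EIF4A1 at 0.45, RRM2 0.03, FOXM1 0.01, CDK1 0.07, KIF4A 0.05, BBC3 0.47, CEBPG 0.06, PHGDH 0.12 and HSP90AA1 0.18. Still at 24 h it put ACLY at 0.09, SREBF2 0.15, EBP 0.37, ATP5F1B 0.34, CYC1 0.23, SDHB 0.25, H2AX 0.26, B2M 0.21 and HLA-E 0.18. Further at 24 h it put PSMB9 at 0.11, DUSP2 0.03, IER2 0.21, VCAN -0.01 and G1/S and DNA replication 0.37. At 36 h this put IRAK1 at 0.41, MYD88 0.38, PIM1 0.50, MYC 0.20, CD83 0.48, IL10RA 0.28, CD79B 0.02, CD81 0.27 and BTG2 0.03. Also at 36 h it put ATP5MC1 at 0.27.

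Centring on the median of the tested genes called 12436 genes over the mean of the times, 7799 at 6 h, 7633 at 12 h, 8093 at 24 h, 10390 at 36 h, 1263 between the lines and 489 for 36 minus 24 h. It called 20 lists over the mean of the times, 17 at 6 h and 18 at 36 h. The opposite sign was found for 73 cases by the same count, and lists that lost their call with a change of sign are not among them. Over the mean of the times this put MYD88 at 0.11, NFKBIA 0.23, PIM1 0.29, IRF4 0.31, SPIB 0.54, MYC 0.34, CD83 0.20, BCL2A1 0.25 and MX1 0.28. For that mean it put MCL1 at 0.21, HGF -0.15, LTB 0.01, HERPUD1 0.26, SSR4 0.22, MCM7 0.35, LIG1 0.11, RRM2 0.05 and EXO1 0.03. Still over the 4 times it put CDK1 at 0.04, KIF11 0.06, BUB1B 0.09, TP53INP1 -0.11, PLK3 0.10, GDF15 -0.15, ATF5 0.02, HSPA5 0.00 and HSP90AA1 0.17. With all times averaged it put DNAJA1 at 0.25, SREBF2 0.06, ATP5F1B 0.30, NDUFA9 0.10, H2AX 0.17, CD74 0.05, B2M 0.26, GZMA -0.26 and VCAN -0.28. Over all times it put ITGAM at -0.19, G1/S and DNA replication 0.21, G2/M and mitosis 0.15, apoptosis regulators of the BCL2 and IAP families 0.15 and amino acid stress response (ATF4) and unfolded protein response 0.15. At 6 h this put SUMO2 at 0.08, IRF4 0.26, SPIB 0.41, MCM7 0.34, NQO1 -0.32, VCAN -0.32 and amino acid stress response (ATF4) and unfolded protein response 0.14. At 12 h this put PIM1 at 0.28, B2M 0.15, VCAN -0.26, plasma cell differentiation 0.18, G2/M and mitosis 0.11, oxidative phosphorylation 0.35 and MHC class I presentation 0.17. At 24 h this put PIM1 at 0.37, SPIB 0.52, MYC 0.38, EIF4A1 0.26, BBC3 0.27, EBP 0.18, ATP5F1B 0.15, CYC1 0.04 and SDHB 0.06. Also at 24 h it put H2AX at 0.06, B2M 0.02, IER2 0.02, VCAN -0.20 and G1/S and DNA replication 0.18. At 36 h this put PIM1 at 0.27, IL10RA 0.05, CD81 0.04 and ATP5MC1 0.03.

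The mean of a gene's probes put NPM1 at -0.02 over the mean of the times, -0.06 at 24 h and -0.07 at 36 h, HSPA5 at 0.01 and HLA-C at 0.00 over the mean of the times, because the probes of these genes disagree. Leaving out the 24 h arrays put CCL3 at 0.02 over the mean of the other times, and leaving out the 36 h arrays put it at -0.65. None of the 68 named genes past the threshold between 36 and 24 h took the opposite sign under these settings.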

Other observations

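The tests in this part were planned, apart from those on the 36 and 24 h difference and the exact permutation of list medians, which were chosen only after the data were seen.

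ACLY, which makes the acetyl units of fatty acids, was at -0.32 at 24 h, ELOVL6, which lengthens them, at -0.31 and HSP90AA1, a cytosolic chaperone, at -0.51 (adjusted p = 0.0275 by limma), though median centring put ACLY at 0.09 and HSP90AA1 at 0.18 and the cholesterol list was at 0.01 without OCI-Ly3. Between 24 and 36 h ACLY rose by 0.48, INSIG1, a sterol sensor partner, by 0.52 and the transferrin receptor gene TFRC by 0.86. FTH1, which codes for ferritin, rose by 0.60 and GCLM, an enzyme of glutathione synthesis, by 0.50. The list of cholesterol and fatty acid synthesis was at -0.11 at 24 h (adjusted p = 0.00201 by camera, adjusted p = 0.599 with an estimated correlation) and at 0.02 at 36 h (adjusted p = 0.407). The cytosolic heat shock response was at -0.10 at 24 h (adjusted p = 0.0065 by camera, adjusted p = 0.361 with an estimated correlation; 0.34 with median centring) and at 0.03 at 36 h (adjusted p = 0.235). Histone genes were at 0.16 at 36 h (adjusted p = 0.00596 by camera, adjusted p = 0.771 with an estimated correlation), with H4C3 at 0.85 (SD 0.30, n = 4, adjusted p = 0.000754 by limma), but the list missed the threshold without OCI-Ly10 (0.07) or HBL1 (0.13).

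Cell cycle lists were below 0 at 12 and 24 h, but above 0 with median centring (G1/S 0.26 and 0.37, G2/M 0.30 and 0.21). RRM2, which makes DNA precursors, was at -0.40 at 24 h (SD 0.22, n = 4, adjusted p = 0.0316 by limma), although median centring put it at 0.03, and it rose by 0.63 between 24 and 36 h, as did TYMS by 0.53 and the mitotic kinase AURKB by 0.53. By exact permutation over the times no list passed (lowest p = 0.00651, adjusted p = 0.13, for the amino acid stress and unfolded protein response), with p = 0.0231 for NF-kB targets and p = 0.0188 for immediate early genes.

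The 8 sign patterns of the 4 lines, the real one included, are too few for a share under 0.05. Counting the real one, 1 reached its number of genes over the mean of the times (2292, highest other 0), 2 at 6 h (128, highest other 203), 1 at 12 h (291, highest other 0), 1 at 24 h (1506, highest other 0) and 1 at 36 h (419, highest other 0). A constant dye effect would favour the real pattern just as a change in expression would. For 36 minus 6 h all 35 splits of the 8 arrays gave as many as the 0 found by limma, where 1916 genes had an unadjusted p under 0.05. The split of TMD8 and OCI-Ly10 against HBL1 and OCI-Ly3 called 579. Of the 8 that part all 4 pairs, the one with the 2 OCI-Ly3 arrays exchanged called 151. The line was a fixed block in these fits, so the 2 counts do not show a constant difference between lines. Their cause was not tested. Without OCI-Ly3 the difference of 36 and 6 h itself called 309, and each line had its own slide. Between the lines 100 of 100 drawn orders gave as many as the 0 found by limma, with 1792 genes at unadjusted p under 0.05, and the highest draw called 2.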
